A study of Mus musculus with 2 samples.

How the data were processed

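Whole uteri were taken from female mice on postnatal day 21, and polyA RNA was sequenced from 2 libraries. A pool of Ube2i f/f uteri gave 1 library and a pool of Ube2i d/d uteri gave the other. Total RNA was extracted with TRIzol and libraries were prepared with the TruSeq RNA kit, per the labels' protocols. How many animals entered each pool, and how the deletion was driven, are not given in the sources used here.

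The deposited files list 1 FPKM value (fragments scaled to transcript length and to the total of mapped fragments) per gene symbol and library. The submitters' processing notes name HISAT2 2.2.1, Cufflinks 2.2.1 and the mouse build mm10, without roles or settings; the unit was taken from the tool names and the values, which are not whole numbers. The gene annotation, strand setting and read length are not given in the sources used here. FPKM divides by transcript length, so a library in which long transcripts yield fewer fragments gives them lower values throughout. The files hold no values per exon or isoform.

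Both libraries listed the same 20634 symbols, and 0 symbols stood on several rows. The ratio of each symbol was log2((d/d + 1)/(f/f + 1)), with a pseudocount of 1 FPKM, which understates the ratio of low genes. The 12769 symbols with at least 1 FPKM in at least one library are called measured. Higher or lower in d/d means at least 2-fold on this scale. With 1 library per genotype there was no replicate spread, no test and no p-value, and every difference describes these 2 libraries without a replicate check.

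Before the data were examined, 53 gene lists were fixed, covering SUMO and hormone pathways, uterine cell types, tissue that a dissection can carry over, signalling, proliferation, immunity, metabolism and technical checks. For each of the 48 lists with at least 5 measured members, the median ratio was set among the medians of 10000 random lists of the same size. These were drawn from genes matched on mean expression in 20 bins. The percentile is the share of random lists with a lower median, and a list was called apart at or below 2.5 or at or above 97.5. Genes are not replicates, so a percentile describes these libraries only.

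Genes to be named were also fixed beforehand. They were Ube2i, Sumo1, Sumo2, Sumo3, Sae1, Uba2, Esr1, Pgr, Ar and Nr3c1, then the 15 highest and 15 lowest ratios among symbols with at least 5 FPKM in at least one library. Predicted models, small RNAs, pseudogenes and replication-dependent histones were left out of that ranking, which removed 31 higher and 16 lower symbols. Each list added up to 4 members with the largest absolute ratio, with the fourth place given to the strongest member of the opposite direction where it was 2-fold apart.

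The ratio was found to fall with transcript length after the files were examined, so several length corrections were added then and are reported beside the values as deposited. Transcript length and GC content came from GENCODE mouse release M21 on the same mouse build, for the longest principal coding transcript of each gene, and 12763 measured symbols matched. The length-adjusted ratio is the residual from a lowess curve (span 0.3) of ratio over log2 length, and a trend with GC content remains in it. Further corrections removed length and then GC content, length taken from the longest transcript of any kind, or length and then mean expression, and another drew random lists matched on length and expression. The principal transcript is short for some genes, including Vegfa at 654 nt and Fst at 1113 nt, so ranges over the corrections are given where they matter. Which transcript length and which corrections to use was settled while values were being looked at, and all of those tried are reported.

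Reads shared between genes were gauged as the percent of 31-mers of a gene's principal transcript that occur in transcripts of another gene. A value of at least 20% marks a gene as uncertain. The alternatives fixed beforehand were pseudocounts of 0.1 and 5 FPKM, no filter, a filter of 5 FPKM, 3 rescalings of the d/d library, 10 expression bins, and lists without shared members. All values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

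The procedure was tested on simulated d/d against f/f data. The simulated noise was smaller than the spread in the data (SD of the log2 ratio 0.56 after length removal). The simulated trend was also removed with the same kind of curve that made it. The rates below therefore check the procedure and are not error rates for the data. With a length trend like that in the data, over 12600 genes, 6.87% of unchanged genes came out 2-fold apart as given and 0.0645% after the trend was removed. Lists of unchanged long genes fell outside the 95% range in 100% of draws as given and in 4% after removal. Changed genes were recovered in the right direction in 78% of cases as given and 89% after removal at a log2 change of 1.5, and in 100% of both at a log2 change of 3. FPKM tables carry no read totals. The most common product of low FPKM values and transcript length was taken as 1 fragment. On that assumption, 1 FPKM in a 2000 nt transcript corresponds to about 32.5 fragments in f/f and 35.4 in d/d.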

Results

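RNA-seq was performed on whole uterus from mice at postnatal day 21, with 1 pooled library from Ube2i f/f animals and 1 from Ube2i d/d animals. Ube2i encodes the conjugating enzyme that attaches SUMO proteins to their targets, and the series describes the d/d uterus as deleted for it. The comparison asked which transcripts differ in the prepubertal uterus when this gene is deleted. The f/f library held 12441 symbols at 1 FPKM or more and the d/d library 12141. If the most common product of low FPKM and transcript length is 1 fragment, the depth of both was close together. It would be about 32.5 fragments in f/f and 35.4 in d/d for 1 FPKM in a transcript of 2000 nt. The most common d/d to f/f ratio among 318 very low genes was 0.988, with 51 of them within 0.15 of it in log2. Values below are given in the order f/f, d/d, and none of them has a replicate check.

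Genes far lower in the d/d library included the BMP-family ligand Gdf7 at 90.5 FPKM in f/f and 4.58 in d/d, the transcription factor Klf5 at 26.4 and 2.1 FPKM, the Wnt ligand Wnt16 at 33.5 and 6.21 FPKM, and follistatin (Fst), which binds activins, at 9.29 and 1.03 FPKM. Among 26 oestrogen-responsive genes, 11 were lower and 1 higher in d/d as deposited, led by Padi1, Greb1 and Clca1, and the counts, though not all of the genes, were the same with the length trend described below removed. Of 23 smooth muscle markers 7 were higher and 2 lower in d/d as deposited, and 6 and 0 with that trend removed, among the higher the contractile genes Cnn1 at 304 and 941 FPKM and Tpm2 at 364 and 1188 FPKM. Neither list lay outside the 95% range of random lists as deposited, and both were picked after length was removed. Lists outside it as deposited and under all 5 settings that deal with length were replication and mitosis, below, and skeletal muscle and red cell markers, above. The replication list was not below with a filter of 5 FPKM (percentile 78.8). Long transcripts in general were lower and short transcripts higher in d/d, so each ratio is given as deposited and, where this matters, with the length trend removed (length-adjusted). Where a list has a pair of medians, the first is as deposited and the second length-adjusted, each with its percentile among random lists, and where the 5 length settings disagree on whether a list lies outside the 95% range, the number that place it outside follows.

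Ube2i itself measured 76.1 FPKM in f/f and 65.4 in d/d, a log2 ratio of -0.21 and thus within 2-fold. The gene lies on mm10 chromosome 17, 25261916 to 25274622, minus strand, with 8 exons in its principal transcript, and 29.2% of that transcript is shared with other genes. The ratio was -0.20 to -0.81 over the length corrections and -0.059 to -0.83 over 3 rescalings of d/d, so it stayed below 0 in each. Values per gene do not show whether any exon was deleted, so this neither checks the genotype labels nor gives the extent of the deletion.

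The SUMO proteins and their activating enzyme were within 2-fold in both libraries. Sumo1 measured 76.8 and 97.8 FPKM, Sumo2 46.7 and 77.6 (36.7% shared), Sumo3 55.7 and 57.8, Sae1 40.4 and 40.9 and Uba2 44.2 and 31. Of the 26 measured SUMO pathway genes, 7 were lower and 0 higher. The SUMO ligase Ranbp2 measured 17.5 and 3.14 FPKM, the SUMO coregulator Zmiz1 33.1 and 8.66, and the SUMO proteases Senp7 and Senp5 8.63 and 2.85 and 8.72 and 2.92. The median of this list was -0.48 as deposited (percentile 2.49) and -0.21 length-adjusted (percentile 3.31, called below in 1 of 5 length settings), and after adjustment 1 member, Ranbp2 at -1.18, was still 2-fold lower. The call as deposited lay at the limit and held in 5 of 10 alternatives that did not concern length.

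Across measured genes, 750 were higher and 1625 lower in d/d, so 68.4% of those apart were lower, and the median log2 ratio was -0.16. The longer the transcript, the lower was the ratio, with a Spearman correlation across genes of -0.68, and genes are not independent replicates. The decile of shortest genes (225 to 1199 nt) had a median log2 ratio of 0.80 and the longest (6388 nt and over) -0.93, and the trend held 43.9% of the variance. With the trend removed, 385 genes were higher and 439 lower (53.3% lower), and 113 higher and 202 lower genes stayed 2-fold apart as deposited and under 3 length corrections. Rescaling moved the split too, to 1164 higher and 1161 lower with the median set to 0, and to 103 and 4107 with equal totals, which shifted the median to -0.68.

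**Figure D1:**
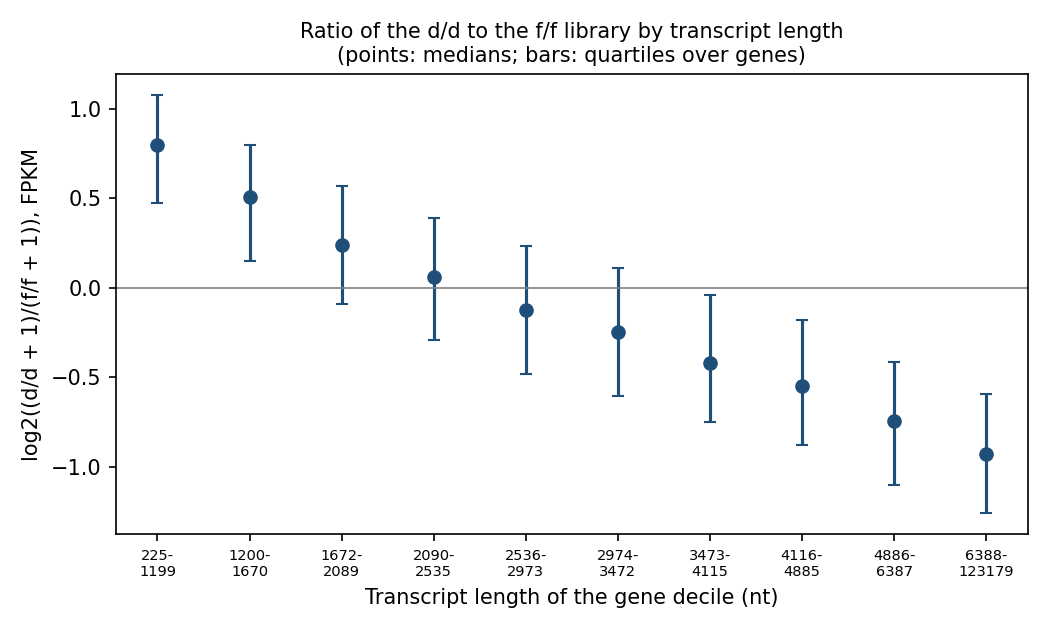
Medians (points) and quartiles (bars) of log2((d/d + 1)/(f/f + 1)) over genes, in deciles of the genes ordered by transcript length in nt. Medians run from 0.80 in the shortest decile to -0.93 in the longest.

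Among the 15 highest-ranked genes were Samd11 at 0.151 FPKM in f/f and 31.6 in d/d, and Cxcl13, the B cell chemokine, at 0.0559 and 8.12 FPKM. The glutathione transferase Gstm7 measured 22.7 and 196 FPKM, an 8.66-fold difference. The receptor kinases Flt3 and Epha8 measured 0.366 and 7.61 FPKM and 0.214 and 6.29 FPKM, and the acute-phase gene Saa3 0.194 and 5.74 FPKM. Extl1, Tcfl5 and Rln3 were listed at 0 in f/f and at 26.3, 5.58 and 5.44 FPKM in d/d. Ass1, which makes argininosuccinate in the urea cycle, measured 3.58 and 123 FPKM, and the ribosomal protein gene Rpl17 464 and 2994 FPKM. Gdf1 (0.258 and 18.6 FPKM), Ndufa12 (13.6 and 98), Ugt1a8 (0.456 and 8.32) and the chemokine gene Ccl21c (3.15 and 22.8) completed the group. Shared sequence makes Ass1 (61.5%), Gdf1 (100%), Ugt1a8 (66%), Rpl17 (46.1%), Ndufa12 (30%) and Samd11 (28.1%) uncertain, and Ccl21c had no match in the annotation.

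Gdf7 led the 15 lowest-ranked genes, 19.8-fold lower in d/d, and it lies on mm10 chromosome 12, 8297918 to 8301954, minus strand, with 2 exons. Klf5 was 12.6-fold lower and lies on chromosome 14, 99298691 to 99315036, plus strand. The ubiquitin ligase Trim56 measured 13.1 and 0.0215 FPKM, Abhd2 15.9 and 0.521, Olfml2a 33.2 and 2.29, and the collagen gene Col6a6 14.8 and 0.684. The Hippo pathway component Mob1a measured 63.1 and 7.5 FPKM, the tankyrase gene Tnks 9.18 and 0.260, the endoplasmic reticulum stress sensor Ern1 8.19 and 0.224, Ddi2 14.2 and 0.843 and Alg10b 10.5 and 0.537. Adnp (12.6 and 0.199 FPKM), Pet117 (38.4 and 2.69), Zbed6 (10.1 and 0.0618) and Nr2c2 (9.89 and 0.490) were also in this group, but 89.1%, 100%, 100% and 46% of their transcripts are shared with other genes. Length-adjusted ratios ranged -5.13 to -4.53 for Gdf7, -2.95 to -2.72 for Klf5, -2.84 to -2.76 for Trim56 and -2.49 to -2.19 for Mob1a over the corrections. Of the 29 annotated ranked genes, 34.5% shared at least 20% of their sequence, against 15.3% of genes at 5 FPKM or more.

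Oestrogen-responsive uterine genes had the lowest median of the 48 lists once length was removed. Padi1, a peptidylarginine deiminase, measured 30.6 and 5.35 FPKM, although 31.8% of its transcript is shared, and the oestrogen receptor target Greb1 measured 6.81 and 0.954 FPKM. Clca1 measured 62.9 and 16.6 FPKM, while the creatine kinase Ckb was higher at 424 and 1056 FPKM (36.8% shared). The median of this list was -0.35 as deposited (percentile 8.32) and -0.68 length-adjusted (percentile 0). It was therefore not called apart in the main analysis fixed beforehand. In the 10 alternatives not concerning length, it was called below in 2 (percentiles 0.89 to 17.55). It was called below under the 5 length settings added later (percentiles 0 to 0.73).

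The receptors themselves were long transcripts. Oestrogen receptor Esr1 measured 108 FPKM in f/f and 46.5 in d/d (-1.20; length-adjusted -0.38), progesterone receptor Pgr 60.8 and 17.1 (-1.77; -0.91) and glucocorticoid receptor Nr3c1 28.6 and 8.86 (-1.59; -0.76). Androgen receptor Ar measured 14.7 and 7.95 FPKM, within 2-fold, and its ratio changed sign from -0.81 to 0.19 on adjustment. Coregulators Ncoa2 and Ncor1 measured 14.2 and 3.2 FPKM and 31.5 and 9.49 FPKM. Of 15 receptor and cofactor genes 8 were lower as deposited and 2 after adjustment, with list medians of -1.08 as deposited (percentile 0.02) and -0.25 length-adjusted (percentile 5.15, called below in 1 of 5 length settings). Progesterone-responsive genes went both ways, with 4 of 20 higher and 3 lower as deposited, and 3 and 3 after adjustment. Il13ra2 measured 0.806 and 4.65 FPKM and Tmem37 2.07 and 7.47, against Fst and the connexin Gjb2 (6.05 and 1.77) lower, and the list medians were -0.10 (percentile 46.2) and 0.12 (76.4).

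Genes of DNA replication and mitosis stood below their random lists. Of 36 measured members, 10 were lower and 0 higher, including cyclin B1 (Ccnb1) at 4.86 and 0.576 FPKM, the spindle protein genes Prc1 at 6.1 and 1.14 and Nusap1 at 3.49 and 0.773, and topoisomerase Top2a at 8.03 and 2.17. Shared sequence leaves Ccnb1 (46.9%) and Prc1 (30.9%) uncertain. The list median was -0.76 as deposited (percentile 0.13) and -0.44 length-adjusted (percentile 0.02), and 9 members were 2-fold lower after adjustment. Of the named members, Ccnb1 and Nusap1 were under 5 FPKM in both libraries, and Prc1 and Top2a were not. With members at 5 FPKM or more in at least one library alone, the list stood at percentile 78.8.

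Immediate early genes, which respond to acute stimuli and to tissue handling, had a median of -0.37 as deposited (percentile 4.93) and -0.36 length-adjusted (percentile 0.16), so they were not called apart as deposited. Klf4 measured 32.4 and 11.4 FPKM, Fosl2 22.3 and 7.23, Nr4a2 2.84 and 1.08 and Klf2 51.5 and 96.5. The p53 target genes, with 1 higher and 3 lower of 27 as deposited and 0 of either after adjustment, had medians of -0.24 (percentile 41.2) and -0.04 (43.5), and their members Eda2r, Rrm2b and Trp53inp1 measured 11.4 and 3.82 FPKM, 7.99 and 2.74 and 15.4 and 5.92 FPKM, against 80.5 and 183 FPKM for the pro-apoptotic gene Bax. DNA damage and checkpoint genes had medians of -0.80 (percentile 3.39) and -0.14 (31.2), with Atm at 3.85 and 1.02 FPKM, Wee1 at 14.5 and 6.38, Mdc1 at 6.46 and 2.66 and Topbp1 at 7.9 and 3.41. Senescence and secretory genes had medians of 0.51 (percentile 99.4) and 0.06 (64), with Igfbp5 at 198 and 58.4 FPKM, Lmnb1 at 20.3 and 8.34, Timp1 at 2.47 and 10 and Ccl7 at 0.377 and 2.89.

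Of the uterine compartments, smooth muscle stood highest in d/d after length was removed. Of 23 measured markers 7 were higher and 2 lower as deposited, and 6 and 0 after adjustment. Myl9 measured 1066 and 3309 FPKM, Cnn1 304 and 941 and Tpm2 364 and 1188, against 59.9 and 19.2 FPKM for Synpo2. The list median was 0.60 as deposited (percentile 81) and 0.68 length-adjusted (percentile 100), so it was not called apart as deposited. Most measured markers of skeletal muscle, which surrounding tissue can carry, were higher as well, and the source of these transcripts was not tested. Acta1 measured 61.1 and 201 FPKM, Ckm 0.348 and 4.9, Tnnc2 0.712 and 7.1 (67.6% shared) and Tnnt3 2.28 and 9.41. Of 17 skeletal muscle markers 7 were measured, and Ckm and Tnnc2 reached 1 FPKM in d/d alone. Of the 7 measured, 6 were higher as deposited and 3 after adjustment. The median was 1.67 as deposited (percentile 100) and 0.96 length-adjusted (percentile 99.99).

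Stromal markers had a median of -0.24 as deposited (percentile 0.02) and -0.12 length-adjusted (percentile 0.89, called below in 1 of 5 length settings). With GC content removed as well it was 0.01 (percentile 24.5), and length-matched random lists put it at percentile 3.79. Stromal members included Pdgfra at 72.5 and 27.5 FPKM, Mme at 19.7 and 9.02, Ecm1 at 23.3 and 52.9 and Thy1 at 123 and 332. Pan-epithelial markers were spread in both directions, 3 higher and 5 lower of 29, with a median of 0.00 as deposited (percentile 23.9) and -0.13 length-adjusted (percentile 2.93, called below in 2 of 5 length settings). With GC content removed as well the median was -0.24 (percentile 0.16), which lies below the range. E-cadherin (Cdh1) measured 53.2 and 19.2 FPKM, Ehf 35.7 and 11.6, Met 8.44 and 2.5 and Cldn7 54.6 and 136, and 0 members were 2-fold apart after adjustment. Gland genes had medians of 0.13 (percentile 48.1) and -0.02 (25.4), with Prss29 at 1.59 FPKM in f/f and listed at 0 in d/d, Sox9 at 2.11 and 0.655 FPKM and Lgr4 at 9.06 and 4.48. Genes whose loss leaves the uterus short of glands had medians of -0.37 (percentile 1.94) and -0.15 (7.04, called below in 1 of 5 length settings), and among them Wnt5a measured 64.6 and 19.2 FPKM and Wnt4 10.3 and 20.5. Squamous epithelium markers had medians of 0.02 (percentile 91.8) and -0.31 (12.4, called below in 1 of 5 length settings), with Lor at 1.91 and 7.72 FPKM, Lgals7 at 3.39 and 8.4, Krt10 at 4.09 and 8.32 and Krt15 at 5.08 and 3.1. Ciliated and oviduct markers had medians of 0.41 (percentile 93.1) and 0.01 (46.1), and Tppp3 measured 573 and 909 FPKM, Rsph1 2.56 and 4.5, Ovgp1 0.969 and 1.78 (36.3% shared) and Ccdc39 1.25 and 0.463 (31.5% shared).

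Endothelial markers had a median of -0.46 as deposited (percentile 0.415) and -0.16 length-adjusted (percentile 3.9, called below in 2 of 5 length settings), with the VEGF receptors Kdr and Flt1 at 27.8 and 7.66 FPKM and 13.8 and 4.44 FPKM, Cdh5 at 82.7 and 32.9 and Ccl21a at 88.9 and 305 (80.6% shared). Pericyte markers had medians of -0.11 (percentile 41.2) and -0.08 (26.8), with Notch3 at 17.2 and 5.92 FPKM, Abcc9 at 22.9 and 10.2, Cox4i2 at 14 and 40.9 and Ndufa4l2 at 21.7 and 55.3. Mesothelial markers had medians of -0.13 (percentile 45.4) and -0.13 (21.1, called below in 1 of 5 length settings), where Wt1 measured 37.7 and 14.9 FPKM, Upk1b 1.72 and 6.19, Krt19 308 and 727 and Msln 1.59 and 3.74. Adipocyte markers were on the high side under both, 0.57 as deposited (percentile 99.5) and 0.39 length-adjusted (percentile 99.4, called above in 4 of 5 length settings), with Cfd at 116 and 480.4 FPKM, Retn at 25.6 and 102, Fabp4 at 82.5 and 204 and Thrsp at 98.4 and 196. Red cell markers were higher in 5 of 5 measured members as deposited and in 0 after adjustment, with a median of 1.62 as deposited (percentile 100) and 0.77 length-adjusted (percentile 99.2), including Hbb-bs at 107 and 395 FPKM and Hba-a1 at 136 and 429. The globin genes share 59.4% to 91% of their sequence. Nerve and Schwann cell markers had medians of 0.14 (percentile 85.6) and 0.39 (96.7), with Mbp at 3.9 and 2.17 FPKM, Prph at 0.498 and 2.77 and Plp1 at 1.66 and 2.64, and ovary markers 0.46 (percentile 94.3) and 0.28 (86), with Foxl2 at 35.6 and 29 FPKM, Inha at 2.67 and 5.34 and Insl3 listed at 0 in f/f and at 1.33 FPKM in d/d.

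**Figure D2:**
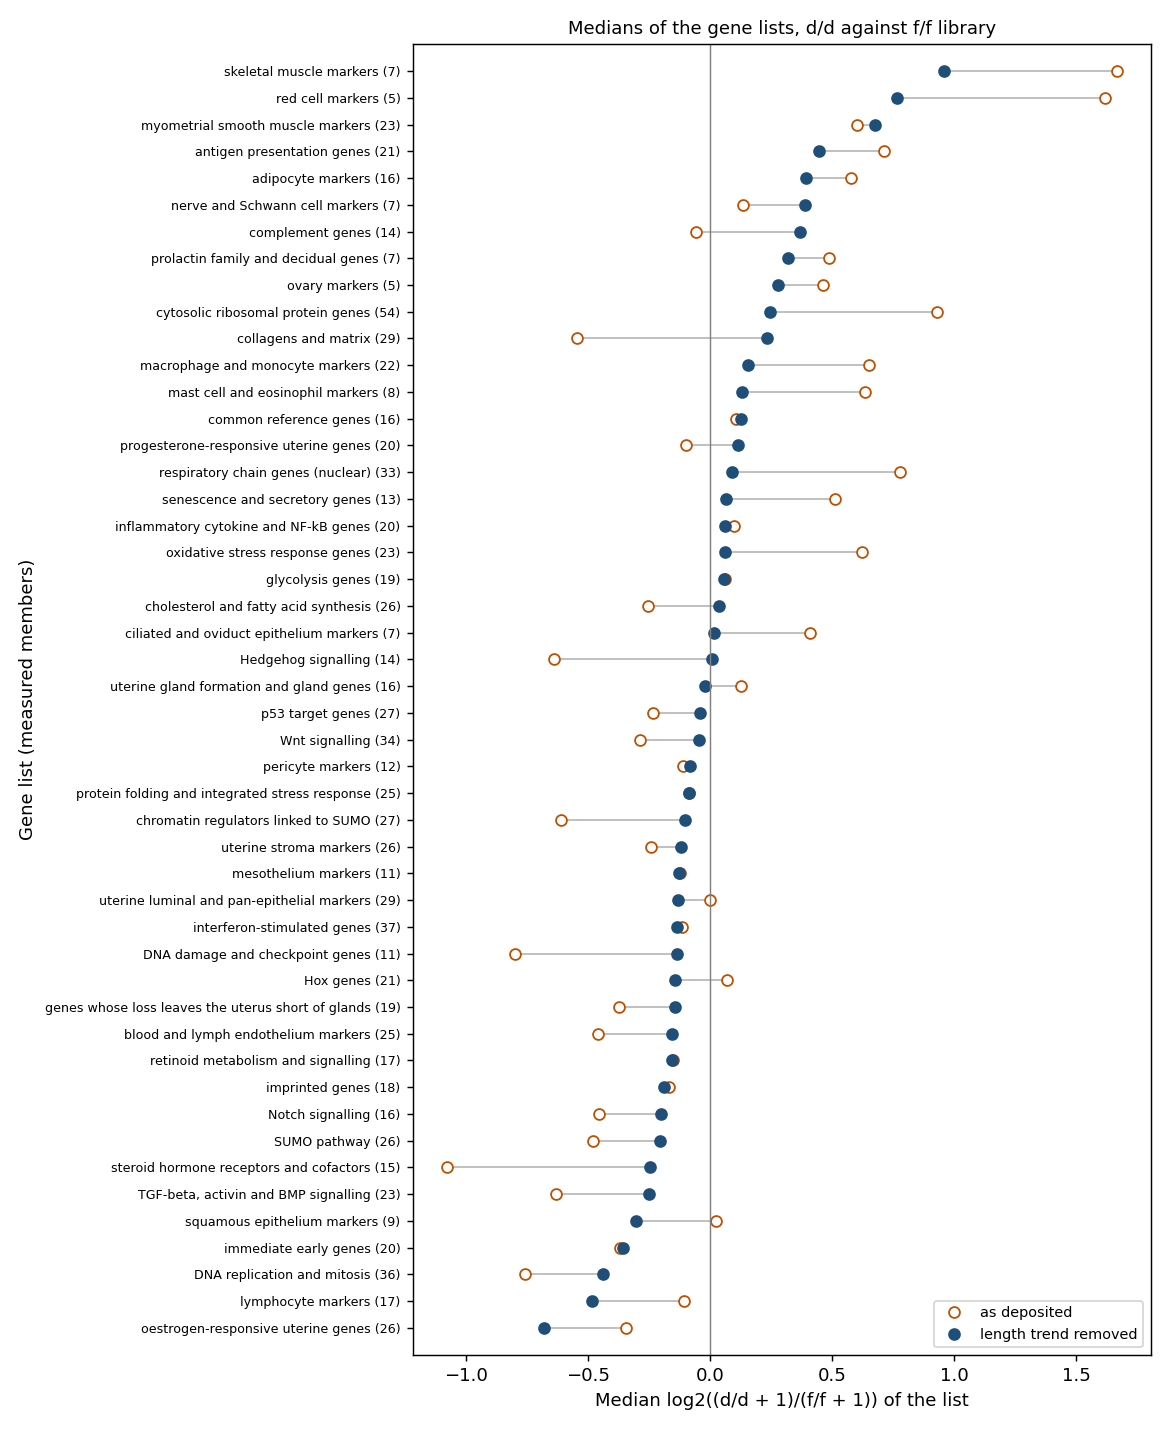
Median log2((d/d + 1)/(f/f + 1)) of 48 gene lists (vertical axis, measured members in parentheses), as deposited (open points) and with the length trend removed (filled points). Skeletal muscle markers lie highest and oestrogen-responsive genes lowest once length is removed, at 0.96 and -0.68.

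Macrophage markers stood above their random lists as deposited, with 6 of 22 higher in d/d and 1 lower, against 1 and 0 after adjustment, and the complement genes C1qa and C1qb measured 65.1 and 168 FPKM and 52.2 and 135 FPKM, Trem2 3.63 and 12.4 and F13a1 5.71 and 2.32. The macrophage list median was 0.65 as deposited (percentile 100) and 0.16 length-adjusted (percentile 90.6, called above in 2 of 5 length settings). It stood at percentile 99.1 with GC content removed as well and at 99.3 against length-matched random lists. Antigen presentation genes had a median of 0.71 as deposited (percentile 97.7) and 0.45 length-adjusted (percentile 99.75, called above in 4 of 5 length settings), with H2-Aa at 119 and 279 FPKM, Cd74 at 272 and 672, H2-DMa at 9.78 and 26.8 and H2-Q7 at 25.2 and 68.6 (52.6% shared). Lymphocyte markers went both ways, with the T cell gene Cd3d at 0.895 and 4.65 FPKM and the B cell genes Cd79a and Cd79b at 0.409 and 3.03 and 1.04 and 4.77 FPKM, against 7.77 and 2.67 for granzyme B (Gzmb), and the list median was -0.11 as deposited (percentile 90.4) and -0.49 length-adjusted (percentile 0.415, called below in 4 of 5 length settings). Of 18 neutrophil genes 3 were measured and 2 of these higher as deposited and 0 after adjustment, where S100a8 and S100a9 measured 0.422 and 4.01 FPKM and 1.59 and 7.58 FPKM, and Mmp9 7.07 and 7.6. Mast cell and eosinophil markers had medians of 0.63 (percentile 99.75) and 0.13 (80.5), with Tpsb2 at 4.11 and 9.36 FPKM and Kit at 4.66 and 1.59.

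Inflammatory and NF-kB genes, besides Cxcl13 and Saa3, included Nfkbia at 83.5 and 45.5 FPKM, and their list medians were 0.10 (percentile 97.3) and 0.06 (73.3). Complement genes had medians of -0.06 (percentile 35.9) and 0.37 (98.5, called above in 2 of 5 length settings), and percentile 52.7 against length-matched random lists, with Cfd highest, Serping1 at 196 and 421 FPKM, Cfp at 4.3 and 11.2 and Cfh at 144 and 72.1 (44% shared). Interferon-stimulated genes had 0 higher and 2 lower of 37 as deposited and 0 of either after adjustment, with medians of -0.12 (percentile 52) and -0.14 (8.13), and Ifi44, Cmpk2, Rsad2 and Cxcl10 measured 10.7 and 4.62 FPKM, 15.2 and 7.04, 10.2 and 4.97 and 4.26 and 8.55 FPKM.

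**Figure D3:**
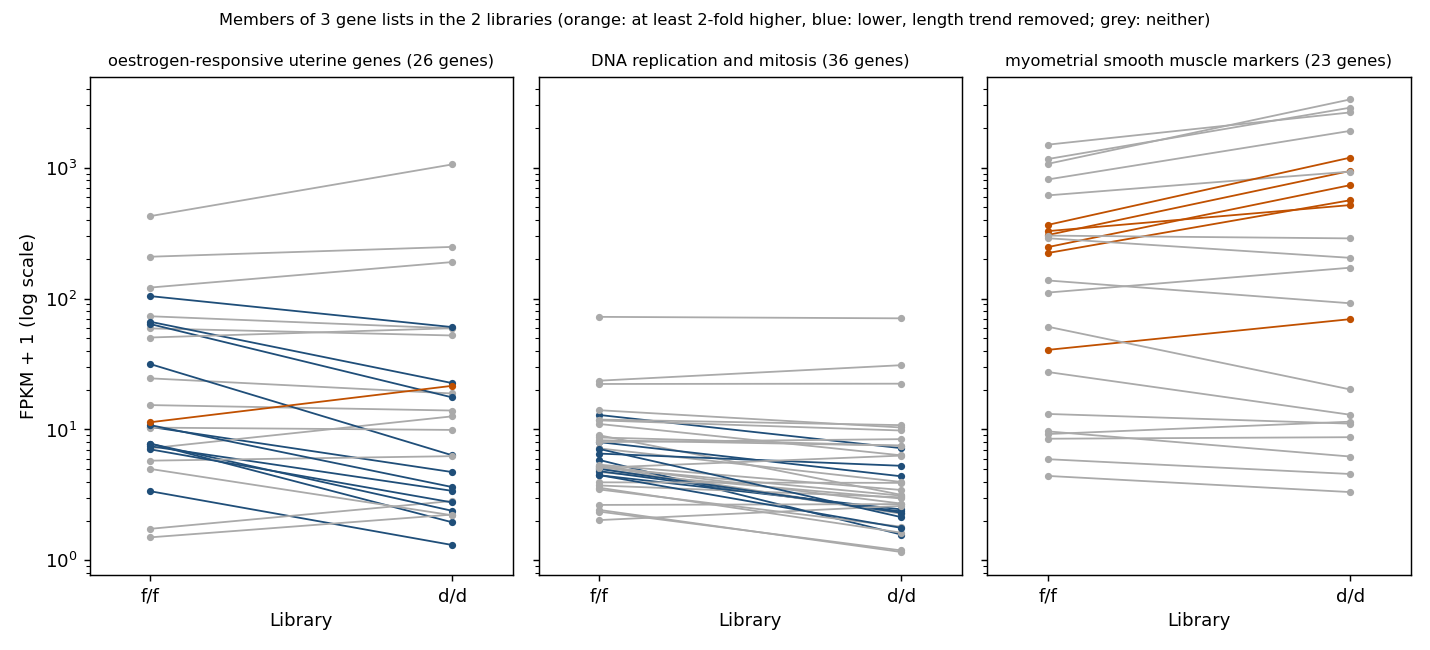
FPKM + 1 on a log axis in the f/f and d/d libraries, with a line per measured gene of 3 lists. Orange and blue lines are at least 2-fold higher or lower after length adjustment, which holds for 1 and 11 of 26 oestrogen-responsive genes, 0 and 9 of 36 replication and mitosis genes, and 6 and 0 of 23 smooth muscle markers.

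Among developmental pathways, TGF-beta, activin and BMP genes were lower in 8 of 23 members as deposited and 4 after adjustment, and higher in 0 under both, with a median of -0.63 as deposited (percentile 0.39) and -0.25 length-adjusted (percentile 1.86, called below in 3 of 5 length settings). Fst, the BMP antagonist Grem2 (15.5 and 4.32 FPKM), the activin subunit Inhbb (9.8 and 2.63) and the receptor Tgfbr1 (12.1 and 4.66) were its furthest members. Wnt genes went both ways, with 3 higher and 6 lower of 34 as deposited, 4 and 2 after adjustment, and medians of -0.29 (percentile 21.4) and -0.05 (34). Wnt16 (length-adjusted -2.62) and Wnt5a (-0.83) were lower as deposited, and Notum (4.29 and 13.2 FPKM, 34.1% shared, length-adjusted 1.33) and Sp5 (1.03 and 4.63, 1.32) were higher. Hedgehog genes had a median of -0.64 as deposited (percentile 1.85) and 0.01 length-adjusted (percentile 54.8), with the ligand Ihh at 22.9 and 51.2 FPKM, the receptor Ptch1 at 18.5 and 7.48, Cdon at 15.3 and 5.76 and Gas1 at 194 and 100.2. Notch genes had medians of -0.46 (percentile 26.7) and -0.20 (15.9, called below in 1 of 5 length settings), with Notch1 at 15.3 and 3.46 FPKM, Notch2 at 15.2 and 5.55 and Rbpj at 22 and 8.66 (24.8% shared). Retinoid genes had medians of -0.15 (percentile 48.1) and -0.16 (13.8, called below in 1 of 5 length settings), with Aldh1a3 at 11.5 and 4.37 FPKM, Cyp26b1 at 4.0 and 1.21, Rdh10 at 19.4 and 9.24 and Rbp1 at 26.2 and 60.4.

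Hox genes had 0 members apart of 21, with medians of 0.07 (percentile 75.8) and -0.14 (9.7, called below in 1 of 5 length settings) and Hoxb3 at 8.07 and 3.91 FPKM (69.5% shared). Collagens and matrix genes had a median of -0.55 as deposited (percentile 0) and 0.23 length-adjusted (percentile 89.1), so the call was lost and the sign turned with length. Fibronectin (Fn1) measured 195 and 42.6 FPKM, Nid1 178 and 52.1, Col15a1 122 and 40.8 and Loxl2 23.4 and 9.04 (47.3% shared), and Fn1 alone of the list was 2-fold lower after adjustment (-1.24). Prolactin family and decidual genes had medians of 0.49 (percentile 93.2) and 0.32 (89.8), with Cryab at 42.8 and 120.4 FPKM (20.4% shared) and Alpl at 0.725 and 3.0.

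Chromatin regulators linked to SUMO had medians of -0.61 (percentile 1.03) and -0.11 (19.2, called below in 1 of 5 length settings), with Atrx at 16.9 and 4.38 FPKM, Rcor1 at 15.2 and 4.93, Mga at 11.2 and 4.41 and Atf7ip at 16.1 and 7.14. Imprinted genes had medians of -0.17 (percentile 32.5) and -0.19 (5.37). Among them Dlk1 measured 12 and 36.3 FPKM, Plagl1 9.51 and 3.06 and Igf2r 31.1 and 11.6, and Phlda2 was listed at 0 in f/f and at 1.63 FPKM in d/d. Germline genes that somatic cells silence were mostly unmeasured, with 4 of 35 measured and 0 of these apart, including Brdt at 1.91 and 2.2 FPKM and Tex15 at 1.91 and 1.36. Of the 2-cell-stage and repeat-linked genes 1 was measured, Arg2, at 7.37 and 3.38 FPKM (23.6% shared).

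Among metabolic lists, cholesterol and fatty acid synthesis had medians of -0.26 (percentile 54.5) and 0.04 (75.1, called above in 1 of 5 length settings), with Dhcr24 at 20.8 and 5.3 FPKM, Stard4 at 7.54 and 2.35, Mvk at 11.9 and 26.6 and Fdps at 15.5 and 39.8 (89.7% shared). Glycolysis genes had medians of 0.06 (percentile 25.4) and 0.06 (44.6), with Pfkfb3 at 24.6 and 8.03 FPKM, Slc2a3 at 19.8 and 7.52, the lactate transporter gene Slc16a3 at 1.41 and 4.64 and Gapdh at 8.99 and 19.7 (84.1% shared). Respiratory chain genes had medians of 0.78 (percentile 94.1) and 0.09 (19.4), with Cox6c at 689.8 and 1685 FPKM and Ndufa2 at 226 and 548. Protein folding and stress response genes had medians of -0.09 (percentile 6.66) and -0.09 (6.14, called below in 2 of 5 length settings), with Slc7a11 at 6.22 and 1.56 FPKM, Dnajb9 at 29.8 and 14.9, Ddit3 at 35.3 and 77.8 and Hspb1 at 367 and 1051 (65.4% shared). Oxidative stress genes had medians of 0.62 (percentile 98.7) and 0.06 (43.1), with Gpx2 at 6.07 and 24.7 FPKM (28.5% shared) and Sod3 at 26.9 and 54.3.

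Technical checks showed the same tilt towards short transcripts. Cytosolic ribosomal protein genes took 22.9% of all FPKM in f/f and 30.0% in d/d, and 21 of 54 were higher as deposited against 3 after adjustment, with medians of 0.93 (percentile 98.2) and 0.24 (77.8). Rps27, Rps15 and Rpl24 measured 6524 and 17027 FPKM, 4098 and 10326 and 1504 and 3704 FPKM, with 98.7%, 63.4% and 82.2% of their sequence shared. Common reference genes had medians of 0.11 (percentile 18) and 0.12 (56.6), with Polr2a at 19.6 and 9.59 FPKM, Ppia at 1019 and 1973 (57.4% shared) and Ubc at 84.4 and 159. Gapdh measured 8.99 and 19.7 FPKM, below Polr2a in f/f, and 84.1% of its transcript is shared, which makes its values uncertain. The sum of FPKM was 621047 in f/f and 956619 in d/d. Of the 24 listed replication-dependent histone genes, 0 were among the deposited symbols, so this list has no values. Of the sex-linked genes, the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y were listed at 0 in both libraries, and the X-linked Kdm6a and Eif2s3x measured 13.1 and 4.04 FPKM and 71.4 and 28.8 FPKM (37.2% of the latter shared).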

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

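The 6 alternatives concerning length, GC content and shared sequence were chosen after the data were seen, and the others before. No paired analysis was possible because each genotype had 1 library and no test was made. No replicate or counting interval existed, so a gene's ratio was taken to move when it shifted by over 1.5-fold or crossed the 2-fold limit. Keeping the highest of several rows per symbol gave no value of its own, since 0 symbols stood on several rows. Genes well under 1 FPKM rest on few fragments, and the ratios of genes near or under 1 FPKM depend on the pseudocount.

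Genes higher and lower in d/d, 750 and 1625 as reported, became 425 and 419 with a pseudocount of 5 FPKM. With the length trend removed they were 385 and 439, with length and GC content removed 335 and 412, with length taken from the longest transcript 480 and 429, and with length and mean expression removed 383 and 421. With equal totals they were 103 and 4107, and 1164 were higher with the median ratio set to 0. The log2 ratio of Ube2i, -0.21, was -0.81 with length and GC content removed and -0.83 with equal totals. Lists above and below the range, 9 and 10 of 48 as reported, were 5 and 5 with length and mean expression removed. They were 5 and 6 against random lists matched on length and expression. With length and GC content removed they were 7 and 14, and 22 lists gained or lost a call. Squamous, mesothelial, Notch, retinoid and Hox lists were called below in that length setting only. The number below was 6 with length removed, and the number above was 5 with length taken from the longest transcript. Of the 48 lists, 3 were below and 3 above the range under all 5 length settings, and 1 and 2 of these were so as deposited too.

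Collagens and matrix turned from percentile 0 to 89.1 with length removed, 80.0 with GC content removed as well, 76.1 with the longest transcript, 93.7 with mean expression removed as well, and 60.5 against length-matched lists. Hedgehog genes turned to 54.8 and, with mean expression removed as well, 64.6. Oxidative stress genes turned to 43.1, to 45.0 with the longest transcript and to 25.6 with mean expression, and senescence genes to 28.7 with length and GC content removed. Removing length alone turned the first 3 of these lists but not the senescence list, which then stood at 64.0. DNA replication and mitosis turned to 78.8 with the filter of 5 FPKM, and the cause was not tested. Some calls made as deposited were also lost among the 10 alternatives not concerning length. Calls held in 5 for the SUMO pathway and in 7 for endothelial, Hedgehog, antigen presentation, oxidative stress and senescence lists. They held in 8 for ribosomal protein genes, and in 9 for mast cell, SUMO-linked chromatin and replication lists. Among named genes 2-fold apart as deposited, the log2 ratios with length and GC content removed of Lgals7, Insl3, Gpx4, Mme and Mga turned to -0.067, -0.17, -0.030, 0.10 and 0.12, and with length and mean expression removed those of Rps27 and Mga turned to -0.030 and 0.00696. Of 50 named genes within 2-fold as deposited, 8 changed sign with length and GC content removed.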

Other observations

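All tests in this part were chosen after the results they bear on had been seen, and the genes of the next paragraph were picked by their length-adjusted ratios.

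Some genes were among the furthest apart once the length trend was removed. The collagen gene Col23a1 measured 7.3 FPKM in f/f and 37.5 in d/d (length-adjusted log2 ratio 2.97), Pde6h 0.789 and 6.69 FPKM (2.88), Dlk1 12 and 36.3 (2.11) and the muscle kinase gene Speg 39.8 and 81.3 (2.03). On the lower side, the laminin-related gene Ntn4 measured 40 and 5.82 FPKM (-2.22), the granzyme gene Gzmc 17 and 4.17 (-2.57), the urothelial gene Upk1a 6.53 and 1.39 (-2.14) and the Ras pathway inhibitor Spred2 31 and 5.78 (-2.09).

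Transcript length correlated more strongly with the d/d to f/f ratio across genes (-0.68) than GC content (0.42) or mean expression (0.34) did. With the length trend removed, the correlation with GC content was still 0.36, so length-adjusted values keep most of that trend. A correction for effective length in short transcripts would leave long genes flat, but the Spearman correlation was -0.42 over 6310 genes longer than 3000 nt. Altered cell makeup alone would move markers of a cell type together, yet the median correlation within cell type lists was -0.66. A trend over all genes gives such values whether or not makeup changed too, so this bears only on makeup as the whole cause. Of 40 lists, whatever their function, 100% had a negative correlation. With -0.68 over all genes this was close to given, so the count does not point to a particular cause. Fewer reads from long transcripts in the d/d library, through RNA integrity or library preparation, would give this pattern. An effect of the genotype on long transcripts cannot be told apart from this with libraries per genotype at 1.

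Oestrogen-responsive genes stood below random lists after adjustment. The list (percentile 8.32 as deposited) was picked after length was removed, which cannot decide on length itself, while GC content as the whole cause of what is left is argued against by a median of -0.79 with it removed as well (percentile 0). A smaller share of epithelium remains open, since the epithelial median was itself -0.24 with both removed (percentile 0.16) and the list median minus it was -0.55, with a 95% bootstrap interval over genes of -1.04 to 0.05. A second look, tried after that interval had been seen to include 0, found 12 of 26 members below the lowest epithelial marker, and without replicates the spread this should be held against is unknown. Lower oestrogen exposure of the d/d pool may also account for the lower list and cannot be told apart from the genotype, with libraries per genotype at 1 and no hormone measure.

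Smooth muscle markers stood above random lists after adjustment. The list (percentile 81.0 as deposited) was likewise picked after length was removed, which cannot decide on length itself, while GC content as the whole cause of what is left is argued against by a median of 0.72 with it removed as well (percentile 100). A smaller share of stroma alone would raise the other compartments alike, but endothelial markers lay -0.95 from smooth muscle (bootstrap interval over genes -1.25 to -0.51). That interval is the spread among marker genes within this pair of libraries, so it does not show whether the difference would recur. With both removed, stromal, epithelial and endothelial medians were 0.01, -0.24 and -0.23, within 0.25 of each other. Epithelial and endothelial markers lay below random lists (percentiles 0.16 and 0.655), and stromal markers did not (24.5). Adipocyte, red cell and macrophage markers lay above, and squamous, lymphocyte and mesothelial markers below. A larger share of muscle in the d/d pool, by dissection or by growth, is a candidate explanation that these values do not decide. Skeletal muscle markers stood above random lists as well, at a length-adjusted median of 0.96 over 7 measured of 17. Of those 7, Ckm and Tnnc2 reached 1 FPKM in d/d alone, which can raise the median. A genotype effect on contractile genes was not tested apart from a larger share of muscle.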
